A study of Homo sapiens with 39 samples.

How the data were processed

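The series holds 39 samples of human U87 glioblastoma cells: 22 poly(A) RNA libraries, 12 small RNA libraries, 4 H3K9me3 ChIP libraries and 1 nanopore direct RNA library of wild-type cells, which is not analysed here. The poly(A) libraries are 16 of wild-type cells (2 per oligonucleotide at 4, 8, 12 and 24 h after transfection) and 6 of 3 miR-29 deletion clones (1 per oligonucleotide and clone at 24 h). The small RNA libraries are 2 with the control guide sgGal4, 2 with the guide against LOC646329, 2 of wild-type cells and 2 of each clone. The ChIP libraries are 2 with each guide. Wild-type cells are the whole cell line and each clone descends from 1 cell, so clones differ from wild type in more than the deletion.

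The authors deposited raw counts per Ensembl gene for each kind of library, 1 column per library. Per the labels and the submitters' processing notes, poly(A) libraries (TruSeq Stranded mRNA) were trimmed with fastp 0.13.1, aligned to GRCh38 with HISAT2 2.1.0 and counted with featureCounts 1.5.0, and DESeq2 1.22 is named for the comparison. For the small RNA libraries (SMARTer smRNA-Seq kit) the notes name FastQC, cutadapt, STAR 2.7 and GRCh38, and for the ChIP libraries (Illumina DNA Prep) FastQC, cutadapt, HISAT2, featureCounts and hg19. The annotation release, the strand setting, the handling of reads with several positions and the ChIP window counted per gene are not given in the sources used here. The values were checked to be whole numbers with a different total in every column. No other normalization was found in them. Symbols and gene lengths came from NCBI tables (RefSeq on GRCh38), by Ensembl identifier for symbols. For poly(A) RNA 60675 identifiers are listed, 41209 with a symbol and 36594 with a count. For small RNA there are 1879 features, 199 with a count, and for ChIP 63640, 55397 with a count.

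Samples were grouped by the condition, clone and time fields of their labels. The free description lines of the clone libraries contradict their titles and condition fields on the oligonucleotide, and the titles and condition fields were used. The titles number the targeting oligonucleotide in wild type and not in the clones, so that it is the same molecule is not certain. Per the labels, libraries of 4 and 8 h share a run name and those of 12 and 24 h another. Wild-type and clone poly(A) libraries are named in different ways and the small RNA libraries of the clones carry another pool name, so genotype may be confounded with a separate series. Whether they were made and sequenced together is not given in the sources used here. LOC646329 appears under no symbol in the tables.

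Total counts per library ran from 34671649 (wild type, control, 4 h, replicate 1) to 73990707 (clone 40, targeting) for poly(A) RNA. Small RNA totals were 362 and 867 (sgGal4), 340 and 561 (targeting guide), 1102 and 598 (wild type), 92 and 57 (clone 15), 54 and 61 (clone 18), and 37 and 494 (clone 40), and whether these columns hold all counts of a library is not given in the sources used here. ChIP totals were 5394232 and 4104857 (sgGal4) and 2094501 and 1193750 (targeting guide). A share of small RNA is given with its exact 95% counting interval, and 3 counts were taken as the floor for a group at 0. These intervals and the floor cover counting error only. In a library of 54 counts a count of 0 allows a share of up to 5.56%, the share of that floor.

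The tests ran in R 4.3.3 with edgeR 4.0.16 (TMM factors, the filterByExpr filter, quasi-likelihood F-test, prior count 2 for log2 fold changes). A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided, within each comparison. Log2 fold changes and standard errors are edgeR estimates unless DESeq2 1.42.0 is named. Wild-type libraries were fitted in 1 model of 8 groups, which gave the effect at each time, its average and a test of its change over time. The 3 clones were fitted with the clone as a block, since each clone supplies both oligonucleotides, and the residual correlation of the 2 libraries of a clone was 0.86, 0.94 and 0.86. For wild type, replicate numbers were not taken as pairs (correlations 0.13, -0.05, -0.01 and 0.17 at the 4 times), nor for small RNA (-0.48) or ChIP (-0.03). The difference between wild type and clones at 24 h came from 1 model of 10 libraries with the clone as a block. Clones and wild type were also compared with control oligonucleotide at 24 h, and for small RNA, where each clone was a group of its own and the mean of the 3 clones was set against wild type. In all 12 comparisons were tested. The common biological coefficient of variation was 0.0819 in wild type, 0.0740 in the clones, 0.377 for clones against wild type and 0.540 for ChIP. MIR29A shares were compared by exact permutation of libraries, with the 2 libraries of a clone averaged first (a choice made after results had been seen), and, over pooled counts, by Fisher's exact test.

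The 22 gene lists were written from general knowledge: DNA replication, mitosis, p53 targets, interferon response, NF-kB inflammation, integrated stress and unfolded-protein response, sterol and fatty-acid synthesis, hypoxia and glycolysis, miR-29 targets, TGF-beta and YAP response, lysosome and autophagy, ribosome biogenesis and MYC, microRNA pathway, chromosome 7q32 neighbours, mitochondrially encoded genes, ribosomal proteins, and markers of astrocytes, neurons, oligodendrocyte lineage, leukocytes and microglia, endothelium and epithelium. Each was tested with camera (limma 3.58.1, correlation 0.01), again with the correlation estimated, and with fry, adjusted over the 22 lists. Camera compares a list with all other genes, while fry tests its own members. Grouping, the models, the lists, the first set of alternatives and the neighbours to report were fixed before the data were examined. ENSG00000226380, the early genes and a second set of alternatives were chosen after results had been seen. The length trend was added later too, before its own values were seen.

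Genes are named in the report by rule: the locus neighbours, and the 10 with the largest fold change in each direction at 24 h and in the average and 3 elsewhere. Also named are up to 4 called members of each list by smallest p (2 where none was called). Those named by fold change had to be called, with a symbol and a mean log2 CPM of at least 3. At a single time, and for clones against wild type, the libraries of the 2 groups could not overlap. In the average the direction had to be the same at all 4 times, and for the difference from the clones in all 3 clones. A few known genes were added from the table of all genes. Alternatives were RLE factors, column totals, no low-count filter, DESeq2, a row-sum filter, an adjusted p under 0.01, a robust prior, a log2 fold change of at least 1, each time alone, models with and without a replicate block, and each library or clone left out in turn.

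The procedure was tested on simulated data with the real dispersions, 100 genes each at log2 fold changes of 1 and 2. At a change of 1 it called 99 for wild type at 24 h, 100 in the clones, 77 for their difference, 3 for clones against wild type and 0 for ChIP. At a change of 2 it called 73 for clones against wild type and 1 for ChIP. False calls were 6.13%, 9.91%, 5.35%, 8.43% and 0% of calls. Camera and fry each found a shifted list of 40 genes (shift 0.5) and called 0 of 20 unchanged lists. Genes were drawn independently there, so this does not cover false calls of lists whose members vary together. A count of 0 for clones against wild type or for ChIP thus says little about changes of 1. The simulated libraries shared a mean per gene and the change was the same in every clone. The 100 called in the clones thus do not give the power for changes that differ between clones, as that of VHL did (-0.91, -2.77 and -3.15).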

Results

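LOC646329 is a long noncoding transcript that carries the hairpins of miR-29a and miR-29b1, small RNAs known to repress collagen and other matrix genes. U87 glioblastoma cells received an antisense oligonucleotide against it or a control oligonucleotide. Wild-type cells were sampled at 4, 8, 12 and 24 h, and 3 clones with a miR-29 deletion (15, 18 and 40) at 24 h. A guide RNA against the same locus was compared with a control guide, sgGal4, for small RNA and for the heterochromatin mark H3K9me3. In wild-type cells the targeting oligonucleotide changed 12172 of 18190 tested genes at 24 h (7907 of 17009 with that time fitted alone), with cell-cycle genes falling and p53 targets rising. In the clones those programs shifted far less, and MKLN1, the coding neighbour of the locus, fell in wild-type cells and did not pass the test in the clones. As lists, the programs stood at adjusted p = 0.439 or above at 24 h with an estimated correlation, and their difference from the clones at 0.634 or above. The p-values of the Fisher tests and of the chi-square test count genes or reads as units. Those of camera also take genes as units, which its preset correlation of 0.01 treats as nearly independent. All other p-values measure only the spread between these samples, which may be technical. None of these p-values measures how other cultures or clones would vary. Genes said to rise or fall the most are those with a mean log2 CPM of at least 3 over the libraries fitted for that comparison.

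The targeted transcript carries no name in the count tables, and the files do not pair LOC646329 with an identifier. Its level can therefore not be given by name in any sample. A single unnamed gene, ENSG00000226380, chosen after its values were seen, was lower in every comparison of targeting with control oligonucleotide, and passed the edgeR test at each time in wild type but not in the clones (adjusted p = 0.129). In wild-type cells its library-scaled counts (CPM, mean ± SD, n = 2) went from 8.15 ± 0.0119 to 3.18 ± 0.530 at 4 h and from 7.92 ± 0.591 to 2.97 ± 0.310 at 8 h. They went from 7.52 ± 0.189 to 4.101 ± 0.304 at 12 h and from 8.56 ± 0.0159 to 4.67 ± 1.75 at 24 h. By library, the counts were 291 and 396 with control and 172 and 170 with targeting oligonucleotide at 4 h, and 415 and 460 against 189 and 172 at 8 h. They were 389 and 341 against 190 and 193 at 12 h, and 368 and 458 against 159 and 354 at 24 h. In clones 15, 18 and 40 the counts were 1909, 2294 and 10400 with control and 764, 162 and 388 with targeting oligonucleotide. The clones started from a higher level, 92.0 ± 86.0 CPM, and ended at 7.11 ± 5.44 (n = 3), with 13.3, 2.92 and 5.15 in clones 15, 18 and 40.

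At the locus, MKLN1, which encodes muskelin, a subunit of a ubiquitin ligase, was lower in wild-type cells at each time and passed the test from 8 h on. Its CPM was 99.3 ± 3.25 with control and 76.9 ± 2.13 with targeting oligonucleotide at 4 h, 95.05 ± 2.85 and 43.3 ± 1.49 at 8 h, 112 ± 7.61 and 31.6 ± 1.31 at 12 h, and 120 ± 6.51 and 49.7 ± 20.9 at 24 h (n = 2 each). The log2 fold changes were -0.39 (edgeR adjusted p = 0.308), -1.13 (adjusted p = 0.000353), -1.84 (adjusted p = 3.0e-06) and -1.27 (adjusted p = 4.3e-05). At 4 h edgeR called MKLN1 with that time fitted alone (adjusted p = 7.4e-06) and with no low-count filter (adjusted p = 3.9e-04). In the clones MKLN1 stood at 115 ± 15.9 with control and 114 ± 12.4 with targeting oligonucleotide (n = 3), a log2 fold change of -0.01 (SE 0.05, edgeR adjusted p = 0.923). LINC-PINT, a p53-induced noncoding RNA whose annotated gene lies between the miR-29 hairpins and MKLN1, fell in wild-type cells by 0.41, 0.38, 0.54 and 0.86 at the 4 times (edgeR adjusted p = 0.0448, 0.00981, 0.000689 and 8.1e-06). The 4 h call of LINC-PINT was lost without any 1 of the 4 libraries of that time (adjusted p 0.188 to 0.285), and the 8 h call without targeting replicate 1 (adjusted p = 0.0711). In the clones LINC-PINT was lower in 3 of 3 (-0.93, -0.69 and -1.29), which did not pass the test (edgeR adjusted p = 0.129).

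**Figure D1:**
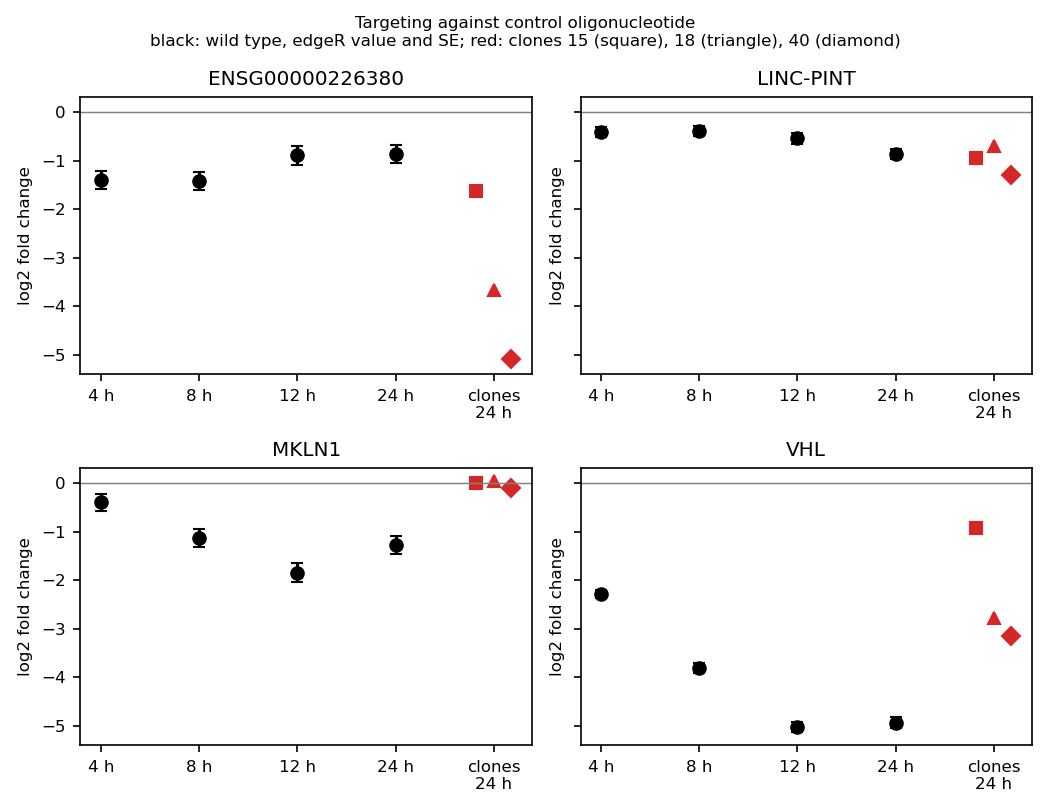
Log2 fold change of targeting against control oligonucleotide (vertical axis) at 4, 8, 12 and 24 h (horizontal axis, hours) for ENSG00000226380, LINC-PINT, MKLN1 and VHL, with edgeR standard errors for wild type and single values for clones 15, 18 and 40. MKLN1 fell by 1.27 in wild type at 24 h and stayed between -0.10 and 0.05 in the clones.

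After 4 h in wild-type cells the response leaned downward, with fewer calls than at the later times. The genes that fell most were VHL, the ubiquitin ligase that degrades hypoxia-inducible factors (-2.28, SE 0.09), TOPORS, a ligase for p53 (-2.17), and ZBED5, a transposase-derived gene (-2.05). CHAC1, a stress gene that degrades glutathione, rose by 1.18. edgeR called 164 genes higher and 513 lower of 18190 (adjusted p = 6.1e-09 for VHL and 4.1e-09 for ZBED5), and 42 and 72 of them by a log2 fold change of at least 1. The list of integrated stress and unfolded-protein genes rose as a set by camera (2 higher and 0 lower, 5 and 1 adjusted over the list alone, median 0.17, camera adjusted p = 1.7e-04, adjusted p = 0.857 with an estimated correlation). Fry called 0 lists at 4 h. The call of CHAC1 (adjusted p = 0.00931) was lost without control replicate 1 (0.0652), control replicate 2 (0.119) or targeting replicate 2 (0.0895). Leaving out any 1 library of this time left 189 to 249 calls, while 4 h fitted alone gave 3547 (1238 higher and 2309 lower) and no low-count filter gave 1292 (350 and 942).

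At 8 h SLC25A34, a mitochondrial carrier (4.54), GDF15, a secreted stress cytokine (3.28), and CHAC1 (3.01) rose the most, while VHL (-3.81), ABTB2, an ankyrin-repeat adaptor (-3.72), and TOPORS (-3.44) fell the most. CDKN1A, the p53-induced cell-cycle inhibitor, rose by 1.52, and p53 targets moved as a set (21 higher and 6 lower, 22 and 6 adjusted over the list alone, median 0.62, adjusted p = 0.745 with an estimated correlation). Of the replication and mitosis genes 17 of 43 and 16 of 51 fell. edgeR called 3263 genes higher and 3613 lower, and 826 and 1019 by a log2 fold change of at least 1. Camera called 5 of 22 lists: p53 targets (adjusted p = 1.6e-05), stress genes (23 higher and 1 lower, also adjusted over the list alone, adjusted p = 5.4e-07), replication (adjusted p = 0.0249), mitosis (adjusted p = 0.0195) and ribosomal proteins (6 higher and 2 lower, 1 and 2 adjusted over the list alone, adjusted p = 0.0144). Each was at adjusted p = 0.745 or above with an estimated correlation. With no library of the other times in the model, 8 h had 9133 calls, and leaving out 1 library left 4101 (targeting replicate 1), 4325 and 4443 (control replicates 1 and 2) and 4976 (targeting replicate 2).

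At 12 h SLC25A34 (5.51), GDF15 (4.52) and GCNA, a germ-cell protease that resolves DNA-protein crosslinks (3.96), rose the most. VHL (-5.03), ABTB2 (-4.96) and FAM111A, a protease of the replication fork (-4.34), fell the most. Stress genes reached their highest median of the 4 times, 0.67 (25 higher and 2 lower, also adjusted over the list alone). edgeR called 5579 genes higher and 5414 lower, and 1631 and 2222 by a log2 fold change of at least 1. Camera called 9 of 22 lists, among them p53 targets (23 higher and 5 lower, 23 and 6 adjusted over the list alone, adjusted p = 6.3e-06), ribosomal proteins (47 and 2, adjusted p = 1.1e-07), mitosis (3 and 33, 3 and 34 adjusted over the list alone, adjusted p = 2.6e-04) and replication (3 and 27, adjusted p = 8.1e-04). The lists of miR-29 targets (8 and 24, adjusted p = 0.0423), lysosome and autophagy (14 and 6, adjusted p = 0.0455), microRNA pathway (3 and 9, adjusted p = 0.0455) and mitochondrial genes (10 and 0, adjusted p = 0.0408) were called by camera at this time too. The smallest adjusted p was 0.676 with an estimated correlation.

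At 24 h replication and mitosis genes fell in wild-type cells and p53 targets rose, each list at adjusted p = 0.439 or above with an estimated correlation. POLA1 and POLE, polymerases of the replication fork, fell by 3.41 and 3.19, and ECT2, which drives cytokinesis, fell by 4.12. Of 43 tested replication genes 2 rose and 41 fell (median -1.21), and of 51 mitosis genes 2 rose and 49 fell (median -1.14). Of 30 p53 targets 26 rose and 2 fell (median 1.44), such as BTG2 (2.99), which halts proliferation, PLK2 (2.62), TP53INP1 (2.52) and SESN1 (2.17), which restrains growth signalling. CDKN1A rose by 2.96. MDM2, the ligase that limits p53, rose from 74.0 ± 6.85 to 166 ± 2.18 CPM (n = 2).

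The single genes with the largest rise at 24 h were SLC25A34 (7.24, SE 0.63), MROH6, a gene of unknown function (5.34), AOC2, an amine oxidase (4.72), GDF15 (4.65) and IL24, a growth-suppressing cytokine (3.999). GCNA (3.60) and NUPR1, a stress-induced chromatin protein (3.40), were also among the 10 largest. SLC25A34 went from 0.252 ± 0.0383 to 37.6 ± 30.9 CPM and GDF15 from 4.21 ± 0.561 to 105.7 ± 86.6 (n = 2), so the targeting replicates lay far apart. RNA5-8SN3 (3.80) and RNA5-8SN2 (3.77) are multi-copy ribosomal genes, and reads shared between copies make their values uncertain. The genes with the largest fall were RASA1, which switches Ras off (-5.34), PIP4K2A, a phosphoinositide kinase (-4.97), VHL (-4.94), NALF1, a subunit of the sodium leak channel (-4.94), and KLHL29, a ubiquitin ligase adaptor (-4.93). PRKCA, protein kinase C alpha (-4.90), FOXN3, a checkpoint repressor (-4.88), MBNL3, a splicing factor (-4.74), FGF13, a channel regulator (-4.72), and TENM4, an adhesion protein (-4.62), followed. VHL went from 29.1 ± 0.523 to 0.945 ± 0.0381 CPM.

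edgeR called 6210 genes higher and 5962 lower of 18190 at 24 h (adjusted p = 2.3e-12 for VHL, 4.3e-11 for RASA1 and 4.7e-07 for SLC25A34). By a log2 fold change of at least 1 it called 2116 and 2786. Scaling by column totals moved the median of all genes by -0.18 and turned the split into 4609 higher and 7335 lower, so the balance of directions rests on the scaling, and 24 h fitted alone gave 7907 calls (3668 higher and 4239 lower). Camera called 8 of 22 lists: replication (adjusted p = 3.7e-11), mitosis (3.4e-11), p53 targets (1.7e-09), ribosomal proteins (1.1e-08), ribosome biogenesis and MYC (0.00212), stress genes (0.0118), hypoxia (0.0195) and microRNA pathway (0.0455). The smallest, for p53 targets, was adjusted p = 0.439 with an estimated correlation. Each of these 8 lists was also called by fry. Of the lists called by camera, fry called 0 of 1 at 4 h, 2 of 5 at 8 h and 9 of 9 at 12 h. It called 6 of 7 in the average and 4 of 7 for the difference from the clones.

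Other programs at 24 h moved less or in both directions. Genes for ribosomal proteins rose (47 higher and 3 lower of 51, median 0.69), with RPL10 (-1.04) and RPL37 (-1.07) among the 3, while of 26 ribosome-biogenesis genes 20 rose and 3 fell, WDR12 (-3.28) most of all. Stress genes had 19 higher and 4 lower of 30 (20 and 4 adjusted over the list alone, median 0.43), with SESN2 (2.65), a leucine sensor, and ATF5 (1.10), a stress transcription factor, among them. Hypoxia and glycolysis genes had 18 higher and 5 lower of 26 (median 0.43), such as the glucose carrier SLC2A3 (1.06), which VHL loss is known to raise. The miR-29 targets fell more often than they rose (11 and 25 of 50, median -0.40, camera adjusted p = 0.0935). Of 13 microRNA-pathway genes 1 rose and 9 fell, among them AGO1 (-1.48), an effector of microRNA silencing, and TNRC6B (-2.98), its partner. The chromosome 7 neighbours had 4 higher and 13 lower of 23 (median -0.47, camera adjusted p = 0.128): EXOC4, of the exocyst (-2.46), CHCHD3, of the mitochondrial cristae (-1.54), PODXL, a sialomucin (-1.49), and NRF1, of mitochondrial biogenesis (-0.89), fell, and CPA4, a carboxypeptidase (2.03), rose.

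The remaining lists were not called by camera at 24 h (adjusted p = 0.0638 or above). Interferon genes had 14 higher and 18 lower of 40 (15 and 18 adjusted over the list alone), with IFIT3 (1.58) up and SAMD9L (-1.59) down, both antiviral. NF-kB genes had 8 higher and 1 lower of 24, with 20 positive values, such as IL1B (1.69), an inflammatory cytokine. Sterol and fatty-acid genes had 11 and 6 of 24, with a median of 0.07 that turned negative under column totals. TGF-beta and YAP targets had 13 and 5 of 23, CCN1, a matrix signal, at 2.16. Lysosome and autophagy genes had 13 and 6 of 23, such as GABARAPL1 (1.69) and SQSTM1 (1.38), which load autophagosomes. The 13 mitochondrially encoded genes had 6 higher and 0 lower, with 13 positive values. Marker lists of cell types were short: astrocyte 3 higher and 2 lower of 9, neuron 2 and 3 of 5, oligodendrocyte lineage 0 and 2 of 5, leukocyte and microglia 4 and 1 of 5, endothelial 1 and 1 of 4 with a median that changed sign under column totals, and epithelial 2 and 0 of 5. MAP2, a neuronal microtubule protein, fell by 3.51, and SLC1A3, the astrocyte glutamate carrier, fell by 1.41. Counts of calls adjusted over the list alone equalled those over all genes for each list given with 1 pair of counts, here and in the other wild-type comparisons.

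**Figure D2:**
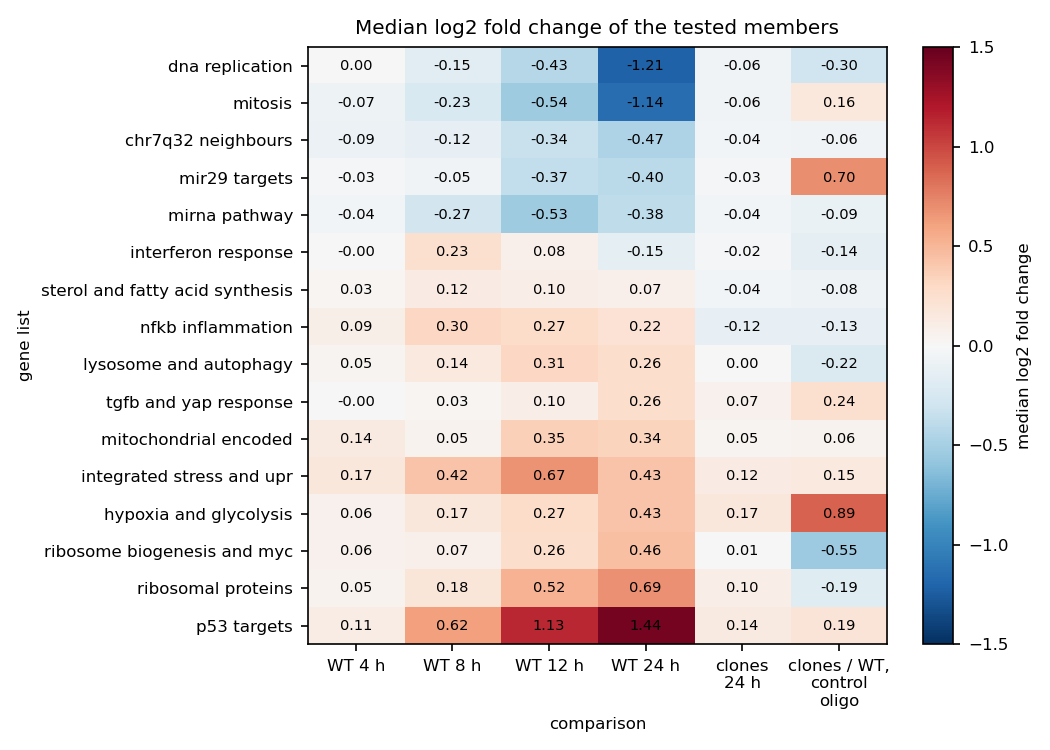
Median log2 fold change (colour and printed value) of the tested members of 16 gene lists (vertical axis) in 6 comparisons (horizontal axis). At 24 h in wild type the p53 targets stand at 1.44 and replication genes at -1.21, against 0.14 and -0.06 in the clones.

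Averaged over the 4 times, VHL (-4.01), ABTB2 (-3.66), C6orf62, of the cytoskeleton (-3.48), and ZBED5 (-3.27) fell the most, and SLC25A34 (4.71), GDF15 (3.15), AOC2 (3.10) and BTG2 (2.30) rose the most. MKLN1 fell by 1.16 on average (adjusted p = 1.1e-07). edgeR called 6807 genes higher and 6176 lower, and 1193 and 1385 by a log2 fold change of at least 1. Scaling by column totals turned the split into 5714 higher and 6969 lower. Camera called 7 of 22 lists, with ribosomal proteins (47 higher and 3 lower, adjusted p = 3.1e-07), mitosis (1 and 46, 1 and 47 adjusted over the list alone, adjusted p = 1.6e-07) and replication (2 and 39, adjusted p = 3.4e-07) the smallest, and none under adjusted p = 0.621 with an estimated correlation. The effect changed with time for 9324 genes by the edgeR test over the 4 times, CDKN1A (adjusted p = 0.000113) and GDF15 (adjusted p = 0.00221) among them. The libraries of 4 and 8 h and those of 12 and 24 h carry different run names in the labels, but each time has its own control under its own run name.

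**Figure D3:**
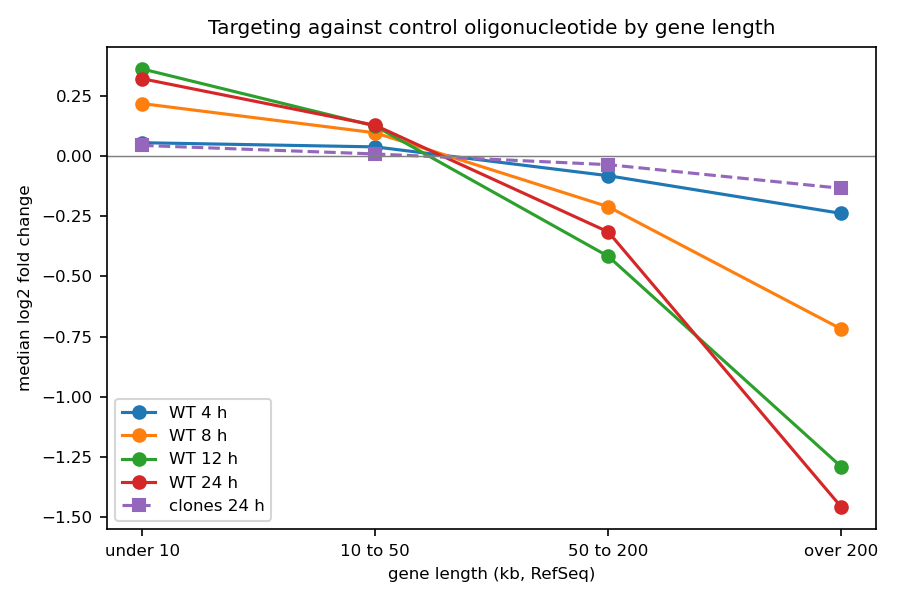
Median log2 fold change of targeting against control oligonucleotide (vertical axis) by RefSeq gene length in kb (horizontal axis) for wild type at 4 times and for the clones. Genes over 200 kb stood at -1.46 in wild type at 24 h and at -0.13 in the clones.

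The response followed gene length. Among 15920 tested genes with a RefSeq length, the 1076 longer than 200 kb had medians of -0.24, -0.72, -1.29 and -1.46 at the 4 times in wild-type cells, and the 4481 shorter than 10 kb stood at 0.32 at 24 h. Spearman correlation with length across genes was -0.31, -0.49, -0.51 and -0.39, and -0.26 in the clones, where the longest genes had a median of -0.13. MKLN1 spans 387 kb, and PRKCA, FOXN3, FGF13 and TENM4 belong to the same long class. Genes are not replicates, so no p-value is attached to these correlations. No list test was matched on length, so a shift of a list is not told apart from this trend. At 24 h genes of 50 to 200 kb had a median of -0.32. The lists of microRNA-pathway genes (-0.38), miR-29 targets (-0.40) and chromosome 7 neighbours (-0.47) stood near it.

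In the miR-29 deletion clones the cell-cycle and p53 programs shifted far less. POLA1 stood at -0.42 and ECT2 at -0.94, against -3.41 and -4.12 in wild type, and CDKN1A stood at 0.11 and GDF15 at 0.30. VHL was lower in 3 of 3 clones (-0.91, -2.77 and -3.15, from 43.4 ± 3.17 to 11.4 ± 10.97 CPM, n = 3), with clone 15 the weakest, as for ENSG00000226380 (-1.63, -3.66 and -5.09). PARP14, of the interferon response, stood at -0.85. None of these passed the test.

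edgeR, with the clone as a block, called 0 of 16831 genes in the clones, with 2558 at an unadjusted p under 0.05 where chance gives 841.55, and a smallest adjusted p of 0.129. DESeq2 called 286 (102 higher and 184 lower), among them LINC-PINT (adjusted p = 2.0e-09) and ENSG00000226380 (adjusted p = 0.00700). Without clone 15 edgeR called 550, LINC-PINT (adjusted p = 0.00842) and ENSG00000226380 (adjusted p = 1.3e-04) among them, and without clone 40 it called 24. With no low-count filter it called 1113 (440 higher and 673 lower). Camera called 6 of 22 lists, each with a small median: p53 targets (0.14, adjusted p = 2.3e-06, 8 higher adjusted over the list alone), ribosomal proteins (0.10, 2.1e-08), hypoxia (0.17, 2.7e-05), stress genes (0.12, 0.00262), mitosis (-0.06, 0.00303) and replication (-0.06, 0.0236, 2 lower adjusted over the list alone). None was under adjusted p = 0.604 with an estimated correlation, and fry called 0 lists.

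The difference between wild type and clones at 24 h was tested directly. EXOC4 (-2.19), CHCHD3 (-1.42), MKLN1 (-1.25) and NRF1 (-0.83) lost more in wild type, and CPA4 gained more (1.70). MKLN1 passed (edgeR adjusted p = 0.0102), but not without wild-type control replicate 1 (adjusted p = 0.0507) or without the clone block (0.0934). POLA1 (-2.98), ECT2 (-3.17), PLK2 (2.49) and SESN1 (1.93) differed likewise, as did SLC25A34 (6.57), UCKL1-AS1, an antisense transcript (5.73), SLC22A23, a transporter (-4.35), FGF13 (-4.25) and RASA1 (-4.24). edgeR called 6712 of 18510 genes, 3038 with the higher value in wild type and 3674 with the lower, and 1160 and 2131 by at least 1. The count was 3696 and 3751 without either wild-type control, 4377 without clone 15, 4316 without clone 18 and 533 with no block. Camera called 7 lists, with replication (1 higher and 38 lower, 1 and 40 adjusted over the list alone, adjusted p = 4.3e-11), mitosis (0 and 47, 0 and 48 adjusted over the list alone, adjusted p = 4.3e-11) and p53 targets (23 and 0, 24 and 1 adjusted over the list alone, adjusted p = 4.8e-10) the smallest and none under adjusted p = 0.634 with an estimated correlation. Wild-type and clone libraries are named in different ways in the labels, which do not say whether they were made together, so genotype may be confounded with a separate series in this test.

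Wild-type and clone effects shared direction. Of the 286 genes that DESeq2 called in the clones, 275 were also called in wild type at 24 h, 88 higher in both and 181 lower in both against 32.9 and 61.5 by chance, and 6 in opposite directions (odds ratio 13.4, Fisher exact p = 7.6e-37, two-sided). In wild type DESeq2 called 10823 of the 16484 genes tested in both, so many shared calls would arise without any relation. The Fisher test covers shared calls in either direction. It counts genes as independent units, which they are not, so its p-value does not measure the spread between samples. The 2 comparisons share no library, controls included. With edgeR the shared count is 0, since it called none in the clones. Across the genes the correlation of the log2 fold changes was 0.48 (Pearson).

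With control oligonucleotide alone, collagen COL4A5 had a higher value in the clones than in wild-type cells and TIMP3 was almost absent, though neither passed in edgeR. COL4A5, a basement-membrane collagen and miR-29 target, stood at 93.9 ± 18.9 CPM (n = 3) against 24.2 ± 0.237 (n = 2) in wild type at 24 h, a log2 fold change of 1.95, and COL5A2, a fibrillar collagen, at 1.41. TIMP3, an inhibitor of matrix proteases, had 1 count in the 3 clone libraries against 1842 in the 2 wild-type libraries, a ratio of column shares of 0.000333 (95% counting interval 8.4e-06 to 0.00186). LINC-PINT stood at 1.40 and ENSG00000226380 at 3.42. COL5A2, LINC-PINT and ENSG00000226380 did not pass either, and edgeR called 0 of 17130 genes, with 1746 at an unadjusted p under 0.05 where chance gives 856.5, and a smallest adjusted p of 0.0586. DESeq2 called 422 (224 higher and 198 lower), and edgeR called 113 without the control library of clone 18, COL4A5 and TIMP3 among them, and 24 with no low-count filter. Camera called 6 lists: miR-29 targets (median 0.70, 9 higher and 1 lower adjusted over the list alone, adjusted p = 5.8e-05), hypoxia (0.89, 1.4e-05), replication (-0.30, 1.1e-06), ribosome biogenesis (-0.55, 1.7e-05), ribosomal proteins (-0.19, 7.1e-04) and lysosome (-0.22, 0.0080, 1 lower adjusted over the list alone). None was under adjusted p = 0.888 with an estimated correlation, and fry called 0. This comparison has the same limit.

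Small RNA from the clones held 2 counts of miR-29a in all. MIR29A took 63 of 1102 and 37 of 598 counts in the 2 wild-type libraries, and 0 of 92, 0 of 57, 1 of 54, 0 of 61, 0 of 37 and 1 of 494 in the 6 libraries of the 3 clones. With the 2 libraries of a clone averaged, the mean share was 0.342% ± 0.508 (n = 3 clones) against 5.95% ± 0.333 (n = 2), with an exact permutation p = 0.1 (two-sided), the smallest that 10 splits can give. The pooled ratio was 0.0428 (95% counting interval 0.00511 to 0.159, Fisher exact p = 6.5e-15, two-sided, over counts). MIR29B1 had 2 counts, in a single sgGal4 library, and MIR29B2 and MIR29C had 0 in every library. With the standard filter only MIR191 (-0.36) and MIR574 (0.36) were tested, and edgeR called 0 of 2 (0 at an unadjusted p under 0.05), while DESeq2 could not be fitted. With no filter edgeR called 10 of 156 features, all lower in the clones, including MIR29A (-5.44, adjusted p = 1.2e-07), let-7b (MIRLET7B, -1.92) and MIR125A (-4.33), a neural microRNA. Libraries this shallow, under another pool name for the clones, limit each of these results, and whether the columns hold all counts of a library is not given in the sources used here. A count of 0 allows a share of up to 5.26% in clone 15 replicate 2 and 8.11% in clone 40 replicate 1 by the floor of 3 counts, and up to 6.27% and 9.49% by the exact 95% counting bound. Pooled by clone, that upper bound was 2.45%, 4.75% and 1.04% in clones 15, 18 and 40.

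With the guide RNA against LOC646329 miR-29a took a smaller share of small RNA. MIR29A had 17 of 362 and 46 of 867 counts with sgGal4, and 9 of 340 and 18 of 561 with the targeting guide. The mean share was 2.93% ± 0.397 against 5.001% ± 0.431 (n = 2 each), with an exact permutation p = 0.333 (two-sided), the smallest that 6 splits can give. The pooled ratio was 0.585 (95% counting interval 0.358 to 0.931, Fisher exact p = 0.0164, two-sided, over counts). The 2 libraries with the targeting guide differed by more than counting error (chi-square of 1.85 per degree of freedom, chi-square test p = 0.00601). The Fisher test leaves that spread out. edgeR called 0 of 15 features (MIR29A -0.64, SE 0.46, adjusted p = 0.759), with 0 at an unadjusted p under 0.05, and DESeq2 called 0.

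**Figure D4:**
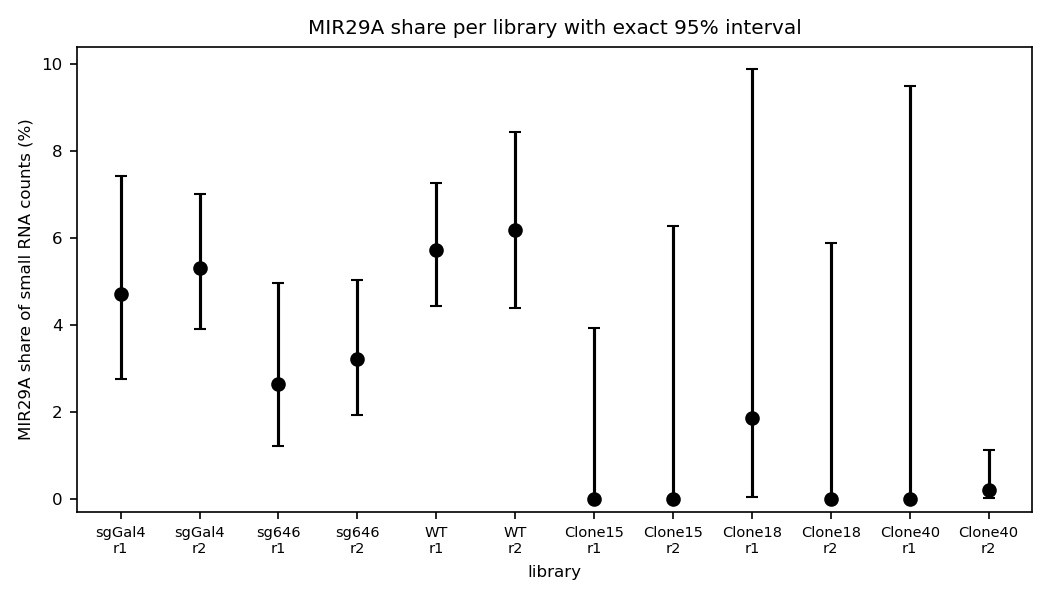
Percent of small RNA counts assigned to MIR29A (vertical axis) in each of the 12 libraries by group (horizontal axis), with exact 95% counting intervals. The 2 wild-type libraries stand at 5.72% and 6.19%, and the 6 clone libraries hold 2 counts in all.

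With the guide RNA against LOC646329, the feature with the smallest p for H3K9me3, a mark of silenced chromatin, was ENSG00000226380, with a higher value, while 27 features had a larger log2 gain. Its counts were 59 and 104 with sgGal4 and 470 and 235 with the targeting guide, or 18.1 ± 10.2 and 210.6 ± 19.5 CPM (n = 2 each). It ranked 1 of 49636 features by p in edgeR, though without passing (3.54, SE 0.52, adjusted p = 1.0), and 1 by DESeq2 (3.60, adjusted p = 8.15e-12). MKLN1 (5, 0, 0 and 0 counts) and LINC-PINT (14, 0, 0 and 0) had too few counts for a change to be read, and PODXL stood at 0.61 and CHCHD3 at -2.52, neither called. edgeR called 0 features, with 1843 at an unadjusted p under 0.05 where chance gives 2481.8, and DESeq2 called 66 (40 higher and 26 lower), or 1 with a row-sum filter. Leaving out the targeting replicate 1 gave 9441 edgeR calls and replicate 2 gave 2594, against 0 without either sgGal4 library, so the count rests on the spread of the targeting pair. The counted window per gene is not given in the sources used here and no input library was analysed here.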

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

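Of the tests in this part, those of gene length, of MKLN1 among long genes and of other splits of the libraries were set before their results were seen, and those of power, of a failed oligonucleotide, of a separate series and of the early genes were chosen only after the result was seen.

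A tested difference of the oligonucleotide effect between times in wild type was found for 9324 genes. Between wild type and clones at 24 h the effect differed for 6712. Among the chromosome 7 neighbours the same test set apart MKLN1 (-1.25), EXOC4 (-2.19), CHCHD3 (-1.42), PODXL (-1.28), NRF1 (-0.83), COPG2 (-0.78), KLHDC10 (-0.65), CEP41 (-0.51) and TNPO3 (-0.51). Each had a lower log2 fold change in wild type. CPA4 (1.70) and ENSG00000226380 (2.73) had a higher one, the latter having fallen further in the clones (-3.54 against -0.85). These neighbours lie up to 2376 kb from MIR29A (EXOC4), and EXOC4 (848 kb) and CHCHD3 (297 kb) are long genes, as MKLN1 is. Among the genes with the largest rise in wild type, or the largest difference in that direction, the test set apart SLC25A34 (6.57), UCKL1-AS1 (5.73), MROH6 (5.04), GDF15 (4.36), AOC2 (4.24), IL24 (3.95), ARHGAP27 (3.38), GCNA (3.19) and NUPR1 (3.02), with RNA5-8SN3 (5.06) and RNA5-8SN2 (5.04), whose reads are shared between copies. Among those with the largest fall, or the largest difference in that direction, it set apart SLC22A23 (-4.35), FGF13 (-4.25), RASA1 (-4.24), PRKCA (-4.11), KLHL29 (-4.01), PIP4K2A (-3.33), FOXN3 (-3.25), NALF1 (-3.03), MBNL3 (-2.94), TENM4 (-2.79) and VHL (-2.58). With 1 library or clone left out, the calls of KLHDC10 and TNPO3 were lost without either wild-type control or any clone, that of PODXL without either control, clone 15 or clone 18, and that of ENSG00000226380 without either control, targeting replicate 2, clone 18 or clone 40. Those of MKLN1, CEP41 and RNA5-8SN3 were lost without control replicate 1, that of CEP41 also without clone 18 and that of RNA5-8SN3 also without control replicate 2.

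The first pattern is that 12172 genes were called in wild type at 24 h and 0 by edgeR in the clones (2558 at an unadjusted p under 0.05, 286 by DESeq2, 1113 by edgeR with no low-count filter). Over the 11347 genes called in wild type and tested in the clones, the clone change was 0.105 of the wild-type change. It was 0.0450, 0.0941 and 0.165 in clones 15, 18 and 40, with the same sign for 60.1%, 69.7% and 73.6%. Too little power would not make the changes smaller, so these values argue against it as the whole account. Power stays open for the count of 0, since VHL (-2.30) and ENSG00000226380 (-3.54) were lower in every clone and did not pass. An oligonucleotide without any action in the clones was argued against by the genes that fell by at least 1 in wild type at 4 h. Their medians in clones 15, 18 and 40 (-0.15, -0.39 and -0.65) lay below all but 1.29%, 1.2% and 0.03% of matched draws. A weaker action stays open. Of these genes 52 of 65 were lower in every clone, where independent signs give 8.13. That count narrows little, since matched genes also had medians under 0 in each clone (-0.09, -0.31 and -0.45). A difference between the wild-type and clone libraries other than genotype cannot be told apart from the deletion, since 0 wild-type libraries are named in the way of the clone libraries and the labels do not say whether both were made together. A role of the deletion itself therefore stays open beside it, as does the higher starting level of ENSG00000226380 in the clones. That level was 8.56 CPM in wild type and a mean of 92.0 in the clones (42.0, 42.7 and 191 in clones 15, 18 and 40).

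For the wild-type count averaged over the times, a chance labelling of these libraries was argued against: only the real split, 1 of 100 drawn from 648, reached its 12983 calls. The highest other had 9058. How other cultures would vary is not covered by these splits. In the clones the 10 splits of the 6 libraries are too few for a share under 0.05, with a real count of 0 and a highest other of 46. Only 4 of the 10 part the 2 libraries of all 3 clones, as the real one does, and the others among these had at most 0 calls.

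The second pattern is that genes that fell by at least 1 in wild type at 4 h, with VHL, TOPORS and ZBED5 in the lead, were also lower in the clones. The median of the 65 with a length was -0.40 in the clones, below all but 0.03% of 10000 draws of genes matched on length and on the 24 h change in wild type (median -0.28, 95% of draws -0.35 to -0.24), and 52 of the 65 were lower in every clone. The match was not complete (medians of -2.79 against -3.18 at 24 h and 135 against 98.8 kb), and with that gap removed by a linear fit the medians were -0.15 and 0.03 (95% of draws -0.0095 to 0.06). That is what the oligonucleotide acting on other transcripts may leave behind, and sequence matches, which would test it further, were not searched. Loss of the targeted transcript stays open: the same genes had a median of -3.18 in wild type at 24 h, but ENSG00000226380, if it is that transcript, was left at 13.3, 2.92 and 5.15 CPM in clones 15, 18 and 40 and at 3.43 and 5.91 in wild type, levels that overlap.

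The third pattern is the fall of MKLN1 in wild type. It lay at percentile 48.5 of the 200 tested genes nearest to it in length (median -1.15 against -1.16 for MKLN1), so MKLN1 falling with the other long genes is what the values show and an effect of the locus on its neighbour is not needed to explain its size. Length bias that differs by chance between libraries stays open too at 4 and 24 h. The difference between the 2 targeting replicates of 24 h followed length with a Spearman correlation of 0.405 in size. That was at least as strong as the treatment there (-0.39) and at 4 h (-0.31). These 2 replicates also lay apart on the main axis of wild-type variation (72.3 and 125). Their difference therefore cannot tell chance bias from an unequal response. The pairs of 4 h itself reached only 0.213 (control) and 0.0813 (targeting) in size. At 8 and 12 h the treatment (-0.49 and -0.51) exceeded 0.405. Control pairs reached 0.231, which the treatment exceeded in size at each time. An effect in cis, with the clones at -0.01, stays open and was not separated from a possible difference in series.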

How the results depend on the processing

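Alternatives set before the data were examined come first here, and those chosen only after the result was seen were column totals for poly(A) RNA, the robust prior, the average without 24 h, the row-sum filter, the crossed block and the DESeq2 overlap. With no low-count filter 4 h gave 1292 calls, the clones 1113, clones against wild type 24 and small RNA of the clones 10. DESeq2 gave 286 in the clones, 422 for clones against wild type and 66 for ChIP, which fell to 1 with a row-sum filter, and left wild-type counts near those of edgeR (933, 6191, 10217 and 11467). Fitted alone, 4 h gave 3547 and 24 h 7907. A replicate block gave 702, 6974, 11015 and 12184 at the 4 times, 13020 in the average and 9384 for the change over time, and 0 for small RNA and ChIP, and without the clone block the clones kept 0 and the difference from wild type fell to 533. Leaving out 1 library or clone gave 189 to 249 calls at 4 h, 4101 to 4976 at 8 h, 8726 to 9323 at 12 h, 10833 to 13477 at 24 h, 12473 to 14192 in the average, 7585 to 12000 for the change over time, 0 to 550 in the clones, 3696 to 9955 for the difference (highest without targeting replicate 1 of 24 h), 0 to 113 for clones against wild type, 0 to 2 for small RNA of the clones and 0 to 9441 for ChIP. A log2 fold change of at least 1 left 114, 1845, 3853 and 4902 at the 4 times, 2578 in the average and 3291 for the difference. Camera calls of lists over the comparisons went from 49 to 0 with an estimated correlation and to 75 with fry, and the shared calls of wild type and clones from 0 to 275 with DESeq2. UBE2H at 24 h (0.02, not called) was reversed without targeting replicate 1 (-0.19) and stood at 0.20 without replicate 2. Of 8844 checks of named values 8295 were the same, 365 weaker, 183 stronger and 1 reversed.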

Other observations

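The tests of ENSG00000226380 and of miR-29 loss in this part were chosen only after the result was seen, as were the small RNA families, the ChIP levels and the library shares.

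FTH1 and SQSTM1 rose in wild-type cells at 24 h with the targeting oligonucleotide (1.46 and 1.38, edgeR adjusted p = 8.75e-07 and 1.3e-08). FTH1, the iron-storing ferritin heavy chain, took 0.566% to 0.668% of counts in the 8 wild-type control libraries, and 1.219% and 1.76% in the 2 targeting libraries of 24 h, against 0.347% to 0.614% in the 6 clone libraries. SQSTM1, an autophagy receptor, went from 928 ± 74.1 to 2409 ± 351 CPM (n = 2). Ribosomal-protein genes took 3.50% to 4.02% of counts in the wild-type controls and up to 5.87% at 24 h. These are shares of a fixed total, so a gain here can stand for a loss elsewhere.

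With control oligonucleotide, the clone values of some genes outside the miR-29 targets lay away from wild type, though edgeR called none of them and genotype may be confounded with a separate series. ALDOC, a glycolytic aldolase, stood at 1.21, OASL, an antiviral gene, at -1.13, NPC1, the lysosomal cholesterol carrier, at -1.497, and MAP2 at -1.31. TIMP3 is on the list of TGF-beta responses and not of miR-29 targets, and its near absence was shared by the 3 clones, with 1 count between them. Higher values of collagens such as COL4A5 (1.95) go the way that loss of miR-29 is known to move them. Loss of miR-29 as a source of the wild-type response at 24 h stays open: the median of the miR-29 targets was -0.40 there, but the members went both ways (25 lower and 11 higher of 50) and camera did not call the list (adjusted p = 0.0935, and 0.645 with an estimated correlation). At 12 h the list had a median of -0.37 and camera called it lower, though not with an estimated correlation. By the labels no small RNA library is of cells given the oligonucleotide, so whether it lowered miR-29 was not measured.

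ENSG00000226380 may be the targeted transcript. It ranked 1 by p among the 49636 features tested for H3K9me3 under the guide RNA, which is what being the transcript that the oligonucleotide and the guide RNA target would give. It was lower with the oligonucleotide in wild type at each time and in each clone, and 24 genes fell more at 4 h. Of 424 genes lower at all 4 times, 264 were also lower in the clones at an unadjusted p under 0.05, and 5 of these had more H3K9me3 at that level (ANAPC1, UPRT, HECTD4, COG3 and this one). The share of all features at that level gives 2.96 of the 192 tested by chance, so this count narrows little. The identifier was picked for such values, the files do not pair it with a name, and the choice therefore stays a hypothesis.

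Small RNA other than miR-29a also differed in share between the clone libraries and the rest. The let-7 family took 14.8% of counts in the other libraries and 4.28% in the clones, miR-21 2.95% and 0.755%, and miR-221 and miR-222 4.07% and 2.14%, while the miR-17 to miR-92 cluster took 1.02% and 1.01% (39 and 8 counts). MIR574 took 5.35% in wild type and 15.2% in the clones, and MIR191 7.88% and 15.8%. The clone libraries carry another pool name, so these shares are not read as effects of the deletion. With no filter edgeR called MIR29A lower in clone 15 (-7.40, adjusted p = 0.0449) and clone 40 (-5.02, adjusted p = 8.4e-05) and not in clone 18 (-3.89, adjusted p = 0.0973).

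H3K9me3 counts were lower over expressed genes. Expressed features are those with a mean of at least 1 CPM in wild-type poly(A) RNA with control oligonucleotide at 24 h. The median was 8.26 CPM over 12983 expressed features and 14.8 over 41575 others with sgGal4, and 7.11 and 15.0 with the targeting guide. Zinc-finger genes named ZNF, a known seat of this mark, stood at 15.1 CPM with sgGal4 against 12.8 for other features. RefSeq lengths cover 64.2% of the tested features, too few to correct for length.

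The spread between replicates set limits to 24 h. The 2 targeting replicates of that time lay at 72.3 and 125 on the main axis of wild-type variation (61.9% of variance), and their counts differed by a chi-square of 63.8 per degree of freedom, against 2.699 to 10.5 for other wild-type pairs. The average without 24 h gave 12570 calls. A repeat of 24 h, and wild-type cells handled beside the clones, would address the limits named here.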
